A study of Mus musculus with 656 samples.

How the data were processed

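The series measured polyadenylated RNA of mouse 3T3 fibroblasts, an established embryonic fibroblast line, by TagSeq, a method that sequences the 3' ends of transcripts. Per the labels, cells received medium with SC-514, an inhibitor of the kinase IKKβ, at 0, 25, 50 or 100 µM for 1 hour, and were then given IL-1β at 1 ng/ml or TNF-α at 10 ng/ml for 15, 30, 60, 120 or 360 min. A group without stimulus or inhibitor was also sampled. The deposited table holds read counts per gene as made by the authors, with 22070 genes and 164 columns, 4 for each of 41 groups. It was checked that all values are whole numbers and that 0 of 240 pairs of columns within groups are identical. The 656 sample records are 4 records for each column, so the column, here called a library, was the unit of every test. No column was left unused. The submitters' processing notes name Bowtie2 and the GRCm38 (mm10) genome, and the tool and annotation used for counting are not given in the sources used here. Gene symbols and positions were taken from GENCODE M21, on the same build, through 21858 gene identifiers that matched, while 212 did not, 29 of them among the genes tested.

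Libraries were grouped by the sample labels for stimulus, inhibitor concentration and time. The labels carry a conflict, because the column prefix in the sample descriptions belongs to the other stimulus than the same prefix in the sample titles. The stimulus label and the description were followed, and libraries are called labelled IL-1β or labelled TNF-α for that reason. Nothing in the labels says whether the 4 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. The labels give no group with inhibitor alone and do not say what vehicle the 0 µM groups received. Chi-squared over degrees of freedom between libraries of a group, over genes with at least 10 counts in the pair of libraries, was 1.08 to 5.49 for pairs without the 2 shallow libraries and 0.981 to 1.01 for pairs with one of them. The unexplained variation of libraries with the same number in other groups of their stimulus had a mean correlation across genes of 0.118, against -0.0392 for other numbers, and 71 of 79 libraries labelled IL-1β and 73 of 79 labelled TNF-α were closest to libraries with their own number. Every pair correlated above 0.1 in 1 of 20 comparisons, so libraries were not treated as paired, and a fit with the library number as a block was run as an alternative.

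Library totals were 928906 to 2469454 counts, with a median of 1282459, except for 2 libraries with 3839 and 12191 counts. Both were kept. Counts scaled to a common library size (CPM) are given as mean ± SD over the 4 libraries of a group. In the other libraries 3 counts equalled 1.22 to 3.23 CPM. A gene without any count in a group was set against a floor of 3 counts over the group, and its change is given as a lower bound. Where a group held 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only.

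Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr by group (10766) were scaled with TMM factors, which were 0.934 to 1.08 and up to 2.44 in the 2 shallow libraries, and 1 robust quasi-likelihood model was fitted over all 41 groups. The biological coefficient of variation was 0.0799, with 123 residual degrees of freedom. Fold changes are those of this model. P-values were adjusted with the Benjamini-Hochberg method within each comparison, and 0.05 was the threshold. The 26 comparisons were each stimulus without inhibitor against the unstimulated group at each time, 100 against 0 µM SC-514 in each stimulus at each time, and F tests over the 5 times for 25 and 50 µM against 0 µM in each stimulus, for IL-1β against TNF-α without inhibitor, and for the difference of the 100 µM effect between the stimuli.

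Tests, gene lists and the rule for named genes were fixed before the data were examined. The rule took genes with a mean of at least 5 CPM in the higher group, an adjusted p under 0.05 and all 4 libraries of 1 group above all 4 of the other, without predicted gene models, ribosomal protein genes and mitochondrial genes. Ribosomal protein genes were recognised by a symbol of Rpl or Rps followed by a digit, so that Rplp1 was not left out. Ranked by fold change, it named 10 rising and 5 falling genes at 60 min and 3 and 2 at other times for each stimulus, and 10 falling and 5 rising genes at 60 min and 3 and 3 at other times for SC-514 at 100 µM. For the IL-1β against TNF-α test and the difference between stimuli it named the 8 genes with the smallest p in each direction. It always named Nfkbia, Tnfaip3, Nfkbiz, Cxcl1, Cxcl2, Ccl2, Ccl7, Il6, Icam1, Vcam1, Fos, Egr1, Ier3 and Ikbkb, and up to 4 members of each gene list with the smallest adjusted p. The 16 lists, written from general knowledge, cover NF-κB components and feedback genes, NF-κB-driven cytokines and chemokines, NF-κB-driven adhesion, protease and effector genes, and anti-apoptotic, immediate early, interferon-stimulated, integrated stress response, NRF2, heat shock, AHR, sterol synthesis, p53, cell cycle, hypoxia and glycolysis, and fibroblast matrix and contractile genes, and markers of other cell types. Lists were compared with all other genes by camera of limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, adjusted over the 16 lists within each of the 20 single-time comparisons. Of 146 calls made so, 48 held with a correlation estimated for each list. The estimates used all libraries, with the 2 shallow ones in which the scores of whole lists were low. They were not made without these, so how far the shallow libraries raised the estimated correlations is not known. List members were also counted with adjustment over the list alone. Other splits of the compared libraries were counted with limma-trend on the same log2 CPM. An NF-κB target score, the mean of log2(CPM + 1) over the 63 tested genes of the 3 NF-κB lists, was compared between inhibitor and 0 µM groups with two-sided exact permutation tests, adjusted over 30 tests. Neither the permutation tests nor the other splits took the library number into account.

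The methods were tested on simulated data shaped like the TNF-α 60 min comparison. With 100 genes changed 1.5-fold and 100 changed 2-fold, edgeR recovered 64 and 85 and called 5 others, limma-voom 62, 82 and 4, limma-trend 61, 82 and 8, and DESeq2 1.42.0 58, 80 and 1. In data shaped like the TNF-α 25 µM F test, edgeR recovered 87 and 99 and called 6 others. With an NRF2 list raised 1.5-fold in data shaped like the IL-1β 60 min comparison, camera gave that list an adjusted p of 5.96e-57 and called 0 of the other lists. Simulated genes were drawn independently of each other, so this cannot tell how camera does with correlated genes.

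Alternatives planned beforehand were RLE size factors, no filter on low counts, the library number as a block, limma-voom, DESeq2, a fit of only the groups compared, the 15 min libraries as baseline, leaving out each library number in every group, other settings of the score, induced genes picked in some libraries and measured in the others, and an estimated correlation in camera. Alternatives added after seeing the data were fits without the 2 shallow libraries, with TMM or RLE, with the log2 library total as a covariate, and without 1 library of a group (IL-1β 25 µM 30 min number 4, IL-1β 25 µM 360 min number 1, TNF-α 0 µM 15 min number 4). RLE uses only genes above 0 in every library, which left 1525 genes for its factors, or 10127 without the 2 shallow libraries.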

Results

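Transcript counts were obtained from mouse 3T3 fibroblasts in 41 groups of 4 libraries each. The groups were 1 without stimulus or inhibitor and 20 for each stimulus label, which covered 4 concentrations of SC-514 and 5 times after stimulation. The series was set up to measure what blocking IKKβ, the kinase that frees NF-κB from its inhibitor proteins, does to NF-κB-driven transcription under either cytokine. Totals per library were 928906 to 2469454 counts, except for 12191 in IL-1β 50 µM 30 min number 1 and 3839 in TNF-α 50 µM 120 min number 1. Number 1 of IL-1β 100 µM had more detected genes than the other numbers at 120 min, 14634 against 13198 to 13350. At 360 min it had 15303 against 13170 to 13529. The median share of mitochondrial transcripts, a sign of RNA quality, was 0.665% in the unstimulated libraries. It was 0.579% at 0 µM and 0.682% at 100 µM in the libraries labelled IL-1β, and 0.638% and 0.667% in those labelled TNF-α. Of 24 marker genes of other cell types, 6 were abundant enough to be tested. Because the labels conflict on the stimulus, IL-1β and TNF-α name a label here and below.

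The effect of IL-1β alone was measured against the unstimulated group. Column names carry a different prefix, or none, for the unstimulated libraries, those labelled IL-1β and those labelled TNF-α. An effect of these library sets that varied with time cannot be told apart from that of a stimulus, and no unstimulated group was sampled at the later times. A set difference alike at all times would be there at 15 min too, where 13 genes were higher and 5 lower. At 60 min 295 genes were higher and 67 lower, and the rise was led by NF-κB target genes. Nfkbia, which encodes the NF-κB inhibitor IκBα and is itself an NF-κB target (chromosome 12, 55489410 to 55492647, minus strand, protein-coding), rose from 140.4 ± 9.48 to 1588 ± 56.0 CPM (SD, n = 4). Il6, which encodes an inflammatory cytokine (chromosome 5, 30013114 to 30019981, plus strand, protein-coding), rose from 11.7 ± 5.67 to 245 ± 39.2 CPM. Cxcl1, which encodes a neutrophil-attracting chemokine (chromosome 5, 90891241 to 90893115, plus strand, protein-coding), rose from 86.2 ± 9.56 to 1198 ± 69.3 CPM. Its neighbour Cxcl2 (chromosome 5, 90903871 to 90905938, plus strand, protein-coding) had no counts in the unstimulated libraries and was at least 63.6-fold higher, at 38.1 ± 11 CPM.

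Of the 22 tested cytokine and chemokine genes of the NF-κB lists, 15 rose and 0 fell at 60 min of IL-1β, and 16 rose when adjusted over the list alone. They included Csf2, which encodes a growth factor of myeloid cells and rose by 7.06 on the log2 scale to 147 ± 12.3 CPM, and the chemokine gene Ccl20, which rose by 6.93 to 258 ± 18.4 CPM. Il1a, the gene of another interleukin-1, was at least 14.0-fold higher. The ratios of Il23a and Csf3, further cytokine genes with 1 to 3 counts in the unstimulated group, were 37.4 (95% counting interval 10.1 to 314) and 39.5 (6.75 to 1590). Of the 20 NF-κB components and feedback genes, 12 rose, with 16 adjusted over the list alone, among them Tnfaip3, which encodes the feedback inhibitor A20 (chromosome 10, 19000910 to 19015657, minus strand, protein-coding), from 4.97 ± 1.68 to 361 ± 28.4 CPM. Of the 21 adhesion, protease and effector genes 13 rose, with 15 adjusted over the list alone, among them Ptgs2, which encodes a prostaglandin-forming cyclooxygenase, with a log2 change of 3.24, and Vcam1, an adhesion molecule gene, with 1.30. Of the 31 immediate early genes 22 rose, with 25 higher and 1 lower adjusted over the list alone, including the transcription factor genes Egr1 (chromosome 18, 34859823 to 34864984, plus strand, protein-coding), with a log2 change of 2.73, and Egr2, with 4.08, and Zfp36, whose product speeds the decay of cytokine mRNAs, with 3.93. Of the 11 anti-apoptotic genes 4 rose, with 7 adjusted over the list alone, including Ier3 with a log2 change of 2.63 and Pim1 with 2.58. Camera called each of these 5 lists higher with an estimated correlation too (adjusted p = 4.28e-06, 5.44e-14, 0.000223, 2.02e-08 and 5.3e-06 for components, cytokines, effectors, immediate early and anti-apoptotic genes).

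Apart from the small AHR list, the other lists had few members past the edgeR test at 60 min of IL-1β. Of the 3 tested AHR genes 2 rose, Nfe2l2 and Cyp1b1, with log2 changes of 0.92 and 0.50 (camera adjusted p = 0.00409 with an estimated correlation). Matrix and contractile genes had 4 of 24 higher and none lower, with 10 higher adjusted over the list alone (camera adjusted p = 2.13e-07, and adjusted p = 0.139 with an estimated correlation). Interferon-stimulated genes had 0 of 29 higher and 1 lower with a list median of -0.32 (camera adjusted p = 0.000929, and adjusted p = 0.598 with an estimated correlation), and cell cycle genes had 0 of 27 past the test with a list median of 0.19 (camera adjusted p = 0.00419, and adjusted p = 0.598 with an estimated correlation). Integrated stress response genes had 4 of 21 higher, hypoxia and glycolysis genes 3 of 19, sterol synthesis genes 2 of 22 and p53 genes 1 of 15, while heat shock genes had 1 of 14 lower. None of the 19 NRF2 genes and none of the 6 markers of other cell types passed the edgeR test at this time.

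Over time, the IL-1β response grew from 13 higher and 5 lower genes at 15 min to 78 and 25 at 30 min, 880 and 469 at 120 min and 1320 and 1012 at 360 min. Early after IL-1β, at 30 min, Nfkbia had reached 544 ± 90.2 CPM, and Fos, which encodes a subunit of the transcription factor AP-1, rose by 2.90 on the log2 scale. Nlrp3, the gene of an inflammasome sensor, was at least 17.4-fold higher at 120 min, when Dact1, which encodes a Wnt pathway regulator, fell by 2.40. By 360 min Ptges, which encodes a prostaglandin E synthase, had risen to 1254 ± 67.4 CPM and Mmp3, which encodes a matrix-degrading protease, from 323 ± 21.1 to 2438 ± 300.0 CPM. Acod1, which encodes the enzyme that makes itaconate, had a ratio of 207 (95% counting interval 36.7 to 8200) and the lectin receptor gene Clec4e 114 (20 to 4530), while Avpr1a, the gene of a vasopressin receptor, had a log2 change of -2.55. At 360 min 14 of 19 NRF2 genes were higher, among them the antioxidant genes Prdx1 and Srxn1 with log2 changes of 0.77 and 1.02 (camera adjusted p = 1.99e-08, and adjusted p = 0.135 with an estimated correlation), and 7 of 15 p53 genes were lower and 1 higher, among the lower ones Ccng1 with -0.42. The other-cell markers had 1 higher and 2 lower, Cd14, a monocyte marker, with 0.69 and Lpl with -0.56 among them.

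Each of the 5 falling genes that the rule named at 60 min lost its call without 1 or more library numbers, and they are not described. The edgeR quasi-likelihood test gave Nfkbia a Benjamini-Hochberg adjusted p of 4.29e-45 at 60 min of IL-1β (log2 change 3.498, SE 0.143), with all 4 libraries above all unstimulated ones. Calls at the early times were unstable, since without library number 1, 2, 3 or 4 in every group 10, 1, 1 and 8 genes were called at 15 min. Without number 2, 3 or 4 there were 45, 44 and 59 at 30 min, without number 2 or 3 there were 238 and 228 at 60 min, and without number 3 there were 854 at 120 min. With RLE factors, 42.9%, 56.5%, 54.6% and 42.7% of the calls at 15, 30, 120 and 360 min were higher, against 72.2%, 75.7%, 65.2% and 56.6% with TMM, and against 71.4%, 72.8%, 63.6% and 56.2% with RLE without the 2 shallow libraries. RLE with all libraries moved the median of all genes by up to 0.12 on the log2 scale, and directions are given relative to the TMM scale.

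The effect of TNF-α alone was measured in the same way. At 60 min 447 genes were higher and 135 lower. Nfkbia rose from 140.4 ± 9.48 to 2160 ± 130 CPM (SD, n = 4), Cxcl1 from 86.2 ± 9.56 to 2130 ± 63.8 CPM and Il6 from 11.7 ± 5.67 to 301 ± 29.5 CPM. Nfkbiz, which encodes the nuclear IκB protein IκBζ needed for secondary NF-κB targets (chromosome 16, 55811375 to 55838899, minus strand, protein-coding), rose from 32.2 ± 7.55 to 484 ± 20.4 CPM. Cxcl2 was at least 190.0-fold higher at 115 ± 5.08 CPM, and Nlrp3 at least 10.8-fold.

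Of the 22 cytokine and chemokine genes 16 rose at 60 min of TNF-α, with 17 adjusted over the list alone. Ccl20 rose to 539 ± 39.1 CPM and Csf2, by 7.83 on the log2 scale, to 251 ± 29.3 CPM. Il1a was at least 32.8-fold higher, and the ratios of Il23a and Csf3 were 118 (95% counting interval 32.3 to 981) and 115 (20.2 to 4600). Components and feedback genes had 15 of 20 higher, with 16 adjusted over the list alone, and adhesion, protease and effector genes 15 of 21, also 15 adjusted over the list alone. Their examples were Tnfaip3, at 571 ± 24.9 CPM, and Icam1, which encodes an adhesion molecule for leukocytes (chromosome 9, 21015985 to 21028817, plus strand, protein-coding) and rose from 0.844 ± 0.706 to 17.9 ± 9.36 CPM. Immediate early genes had 25 of 31 higher, with 27 adjusted over the list alone, including Egr2 and Fos, which rose by 5.07 and 4.72 on the log2 scale. Anti-apoptotic genes had 5 of 11 higher, with 6 adjusted over the list alone, including Ier3 with a log2 change of 3.55. Camera called these 5 lists higher with an estimated correlation (adjusted p = 3.56e-13, 1.73e-07, 5.64e-05, 8.93e-11 and 9.45e-06 in the order given). All 3 tested AHR genes rose (camera adjusted p = 0.000338 with an estimated correlation), with Nfe2l2 at a log2 change of 1.22. Integrated stress response genes had 5 of 21 higher (camera adjusted p = 0.00153, and adjusted p = 0.455 with an estimated correlation) and matrix and contractile genes 6 of 24 (camera adjusted p = 6.81e-09, and adjusted p = 0.0863 with an estimated correlation).

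The TNF-α response counted 9 higher and 11 lower genes at 15 min, 60 and 11 at 30 min, 984 and 550 at 120 min and 390 and 194 at 360 min. Nos2, which encodes the inducible nitric oxide synthase, had a ratio of 252 (95% counting interval 44.9 to 10000) at 120 min and 96.8 (16.9 to 3870) at 360 min, when the chemokine gene Cxcl9 rose from 1.42 ± 0.834 to 48.5 ± 5.42 CPM. Dact1 and Zswim3 had log2 changes of -2.23 and -2.54 at 120 min. Of the 22 cytokine genes 17 were higher at 360 min. Of the 20 components and feedback genes 5 were higher then (camera adjusted p = 0.00355, and adjusted p = 0.442 with an estimated correlation), and Nfkbia stood at 161 ± 11 CPM, a difference that did not pass the test. NRF2 genes had 13 of 19 higher at 360 min, among them Prdx1 with a log2 change of 0.56 (camera adjusted p = 0.049 with an estimated correlation). Of the 29 interferon-stimulated genes 4 were higher, with 15 adjusted over the list alone, among them Gbp2, which encodes an interferon-induced GTPase, with 1.69 (camera adjusted p = 5.08e-14, and adjusted p = 0.169 with an estimated correlation).

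The falling genes named by the rule at 60 min of TNF-α likewise lost their calls without 1 or more library numbers. For Nfkbia at 60 min of TNF-α the edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 2.01e-50 (log2 change 3.94, SE 0.144), with 4 of 4 libraries higher. At 15 min 3, 32, 6 and 7 genes were called without library number 1, 2, 3 or 4, and 6 without TNF-α 0 µM 15 min number 4 alone, and without number 1 there were 46 at 30 min, without 1 or 4 there were 384 and 380 at 60 min, and without 3 or 4 there were 292 and 358 at 360 min. With RLE factors 24%, 58.7%, 50.8% and 49.2% of the calls at 15, 60, 120 and 360 min were higher, against 45%, 76.8%, 64.1% and 66.8% with TMM and 42.9%, 73%, 64.7% and 62.6% with RLE without the 2 shallow libraries.

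**Figure D1:**
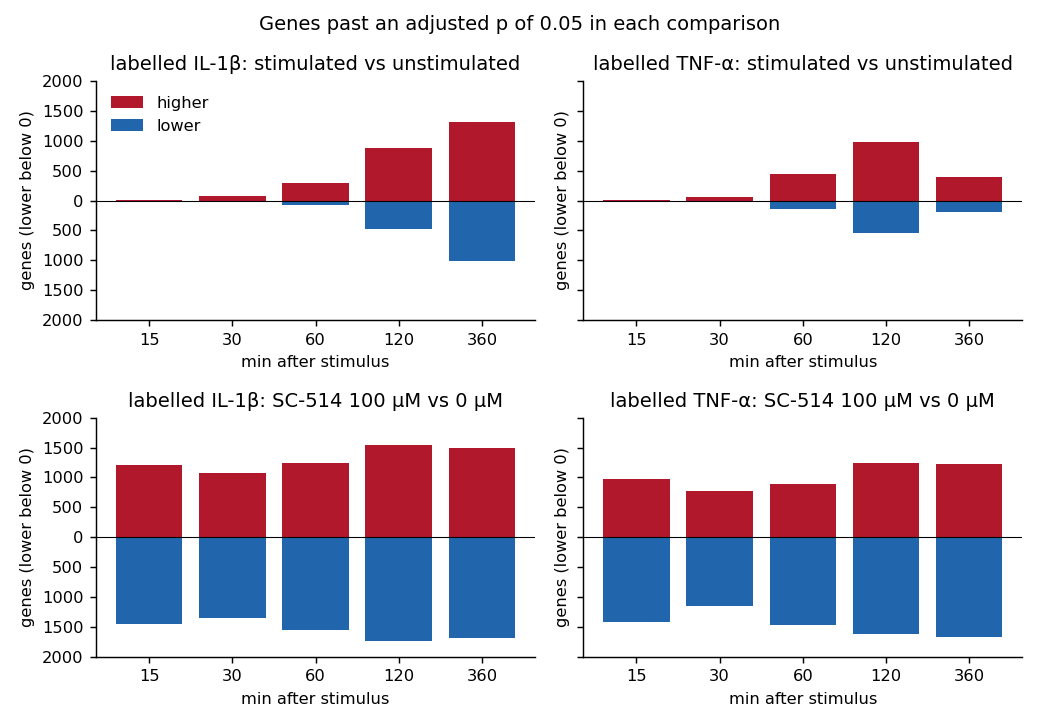
Number of genes past an adjusted p of 0.05 in each single-time comparison, with higher genes drawn above 0 and lower genes below it, by min after stimulus and stimulus label. The stimulus calls grow from 13 higher genes at 15 min to 1320 at 360 min for IL-1β. SC-514 at 100 µM, given 1 hour before the stimulus, has 1210 higher and 1456 lower genes at 15 min of IL-1β.

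Many of the genes raised by either cytokine at 60 and 120 min were shared, while at 15 min 0 were, of 13 with IL-1β and 9 with TNF-α. At 60 min 237 genes were higher with both stimuli, where independent lists would share 12.2, and 20 were lower with both, against 0.84. Both comparisons used the same unstimulated libraries, and with those libraries divided between them 159 genes were higher with both and 3 lower. At 120 min 679 were higher with both (423 with divided controls). At 360 min 313 were (149 with divided controls), of 1320 with IL-1β and 390 with TNF-α, and 155 were lower with both (55 with divided controls), of 1012 and 194. Dividing the controls does not remove a difference between the unstimulated library set and the others.

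IL-1β and TNF-α were compared directly without inhibitor, over the 5 times together, to find where the responses differed. Libraries of the 2 labels also differ throughout in the prefix of their columns. The test cannot tell a difference between these library sets from one between the stimuli. The F test called 1029 genes, 520 with a higher mean in the libraries labelled IL-1β and 509 with a lower mean, and 630 of them had their widest difference at 360 min. Of the 20 components and feedback genes of NF-κB 9 had a higher mean with IL-1β and 5 a lower one, with 16 passing adjusted over the list alone. At 360 min Nfkbia stood at 504 ± 61.1 CPM in libraries labelled IL-1β and 161 ± 11 CPM in those labelled TNF-α, a log2 difference of 1.65, and Tnip1, which encodes a partner of A20, differed by 2.12, Traf1, a receptor adaptor gene, by 2.07 and the protease gene Mmp3 by 1.34. The widest differences in the other direction were in Nfkbiz, with -3.19 at 60 min (53.04 ± 6.95 against 484 ± 20.4 CPM), and in Zc3h12a, which encodes the ribonuclease Regnase-1, with -2.67 at 120 min.

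Ptges, Slc7a2 and Map4k4 also had higher means with IL-1β, and at 360 min they differed by 1.66, 1.73 and 0.76 on the log2 scale. Among the genes with lower means were Cxcl5, a chemokine gene, with -1.82 at 360 min, the homeobox gene En1 with -1.997 at 360 min, and Ier3, Jun and Ier2, which are induced early and differed at 60 min by -0.91, -1.06 and -1.21. Most of the named genes changed sign between times, while Nfkbiz and Zc3h12a were lower with IL-1β at all 5 times. Ptges and Nfkbia differed by -0.65 and -0.44 at 60 min. Ier3, Jun and Ier2 differed by 0.43, 0.62 and 0.43 at 360 min. Ndrg1 and Tnfaip2 had 1.27 and 1.202 at 360 min and -0.54 and -0.51 at 60 min. The mean differences of Ndrg1 and Tnfaip2 turned sign without 1 library number. That of Ndrg1 went from -0.0835 to 0.0453 without number 1. That of Tnfaip2 went from 0.00101 to -0.0113 and -0.0329 without number 2 or 4. Immediate early genes had 19 of 31 lower and 3 higher, with 24 passing adjusted over the list alone. The edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment gave 2.14e-56 for Nfkbiz, 4.2e-38 for Zc3h12a and 6.05e-34 for Tnip1. The rise of Nfkbiz with IL-1β at 60 min was itself small, a log2 change of 0.72 (adjusted p = 0.0143 from edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and was not called without library number 1, 2 or 4 or with log2 library total as a covariate.

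**Figure D2:**
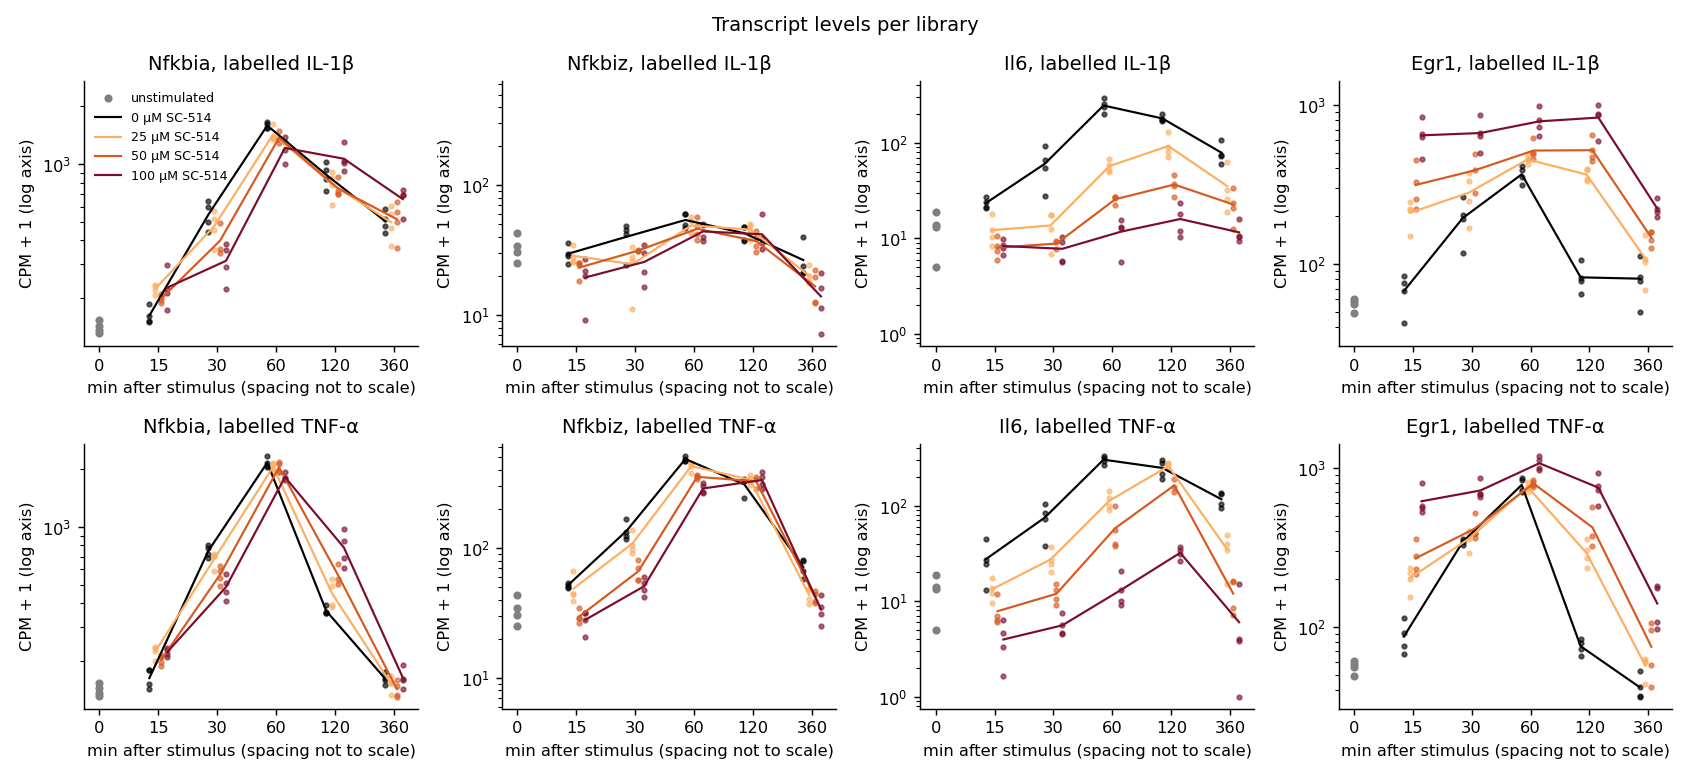
CPM + 1 on a log axis of Nfkbia, Nfkbiz, Il6 and Egr1 by min after stimulus, with points for libraries and lines for group means at each SC-514 concentration, without the 2 shallow libraries. Il6 falls with SC-514 under both stimulus labels, and Nfkbiz reaches 484 CPM at 60 min of TNF-α and 53.04 CPM at 60 min of IL-1β.

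SC-514 at 100 µM was compared with 0 µM in the libraries labelled IL-1β to see how the response differed with the inhibitor. Times count from the stimulus, and the inhibitor had been given 1 hour before it. At 60 min most of the cytokine and chemokine genes fell, and Il6 was at 10.8 ± 4.24 CPM with inhibitor and 245 ± 39.2 CPM without (SD, n = 4), close to the 11.7 ± 5.67 CPM of the unstimulated group. Cxcl5 fell from 654 ± 32.4 to 97.7 ± 14.0 CPM, Icam1 from 10.7 ± 7.56 to 0.814 ± 0.723 CPM and Cxcl2 from 38.1 ± 11 to 3.04 ± 2.10 CPM. Other targets fell less, such as Ier3, Vcam1 and Nfkbia with log2 changes of -0.78, -0.68 and -0.39, and the call of Nfkbia, at 1214 CPM, was lost without library number 3 or 4. Ccl7, another chemokine gene, did not pass the test at 30, 60 or 120 min.

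Of the 22 cytokine and chemokine genes 16 fell and 0 rose at 60 min, also 16 adjusted over the list alone, and camera called the list lower (adjusted p = 0.000347 with an estimated correlation). Il23a, Il1a and Csf3 were lower by ratios of 74.0 (95% counting interval 13 to 2960), 41.5 (7.12 to 1670) and 39.0 (6.68 to 1570). Components and feedback genes had 11 of 20 lower and 2 higher, with 12 lower adjusted over the list alone (camera adjusted p = 1.35e-07, and adjusted p = 0.172 with an estimated correlation), and Tnfaip3 among them fell by 1.96. Adhesion, protease and effector genes had 14 of 21 lower, also 14 adjusted over the list alone (camera adjusted p = 6.61e-12, and adjusted p = 0.122 with an estimated correlation), with Ptges at a log2 change of -1.64 and Mmp3 at -1.29. Anti-apoptotic genes had 5 of 11 lower, with Pim1 at -1.85 (camera adjusted p = 0.0119, and adjusted p = 0.453 with an estimated correlation). Serpinb2, the gene of a serpin family member, had no counts with inhibitor and was at least 23.9-fold lower, and Lce1g fell by 3.94. Dynap was lower by a ratio of 14.6 (3.77 to 126). Cxcl9 fell by 3.73, a call that limma-voom did not make.

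Other transcripts rose with SC-514 at 100 µM. Among the rising genes that the rule named at 60 min were Hist1h1c, a histone gene, at 291 ± 50.5 against 37.3 ± 8.56 CPM and Hist1h2bc at 220 ± 38.1 against 35.4 ± 7.38 CPM, and Hist2h3c2 and Hist1h4i, which rose by 3.31 and 2.58 on the log2 scale. The widest rise among them was that of Fosb, which encodes an AP-1 subunit, from 3.58 ± 1.84 to 45.5 ± 10.8 CPM. At 15 min Egr1 stood at 643 ± 158 CPM with inhibitor and 66.6 ± 18.1 CPM without, and 14 of 31 immediate early genes were higher and 1 lower, also 14 and 1 adjusted over the list alone (camera adjusted p = 9.01e-12, and adjusted p = 0.373 with an estimated correlation). At 60 min 10 of them were higher and 12 lower. Integrated stress response genes had 10 of 21 higher and 1 lower at 15 min, among them Ddit3, which encodes the stress transcription factor CHOP, with 1.78 and Sesn2 with 1.23 (camera adjusted p = 1.07e-05, and adjusted p = 0.448 with an estimated correlation). Heat shock genes had 9 of 14 lower at 15 min, with the chaperone gene Hsph1 at -0.82 (camera adjusted p = 0.000227, and adjusted p = 0.483 with an estimated correlation). P53 genes had 7 of 15 higher and 1 lower at 15 min, with Ccng1 at 0.39 (camera adjusted p = 0.0102, and adjusted p = 0.68 with an estimated correlation). The monocyte marker Cd14 fell by 1.95 at 60 min and Lpl rose by 0.60.

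At 360 min of IL-1β sterol synthesis genes were lower with the inhibitor, 18 of 22 of which fell and 0 rose, also 18 adjusted over the list alone, with Cyp51 at -1.19 (camera adjusted p = 6.95e-10, and adjusted p = 0.248 with an estimated correlation). Hypoxia and glycolysis genes had 11 of 19 lower, among them the growth factor gene Vegfa at -1.21 (camera adjusted p = 2.79e-06, and adjusted p = 0.248 with an estimated correlation). Of the cytokine and chemokine genes 12 were still lower and 1 higher (camera adjusted p = 0.0337 with an estimated correlation), and Mmp3 fell from 2438 ± 300.0 to 254 ± 32.4 CPM. Serpinb2 fell by 5.27, Clec4e was lower by a ratio of 34.6 (95% counting interval 11.5 to 170.0), and Cxcl2 by 42.4 (7.24 to 1710). Rsad2, an interferon-stimulated antiviral gene, rose from 58.0 ± 11.4 to 703 ± 289 CPM, and Rnf225 and Cd209c rose by 3.24 and 2.76. The interferon-stimulated list score at 360 min was higher than at 0 µM by 0.611, 1.09 and 0.725 at 25, 50 and 100 µM, with exact permutation p = 0.343, 0.0571 and 0.0571, and 0.514, 0.171 and 0.171 after Benjamini-Hochberg adjustment over 6 tests, so that none passed. Under TNF-α it differed by -0.059, -0.144 and -0.0462 (adjusted p = 0.914, 0.514 and 0.914). Between these times, Ramp3 fell from 139 ± 13.4 to 12.1 ± 1.96 CPM at 30 min and Mertk rose by 3.32, and at 120 min Grhl1, a transcription factor gene, was at least 13.8-fold higher, Il1f6 at least 7.66-fold lower, and Fos rose by 3.5.

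**Figure D3:**
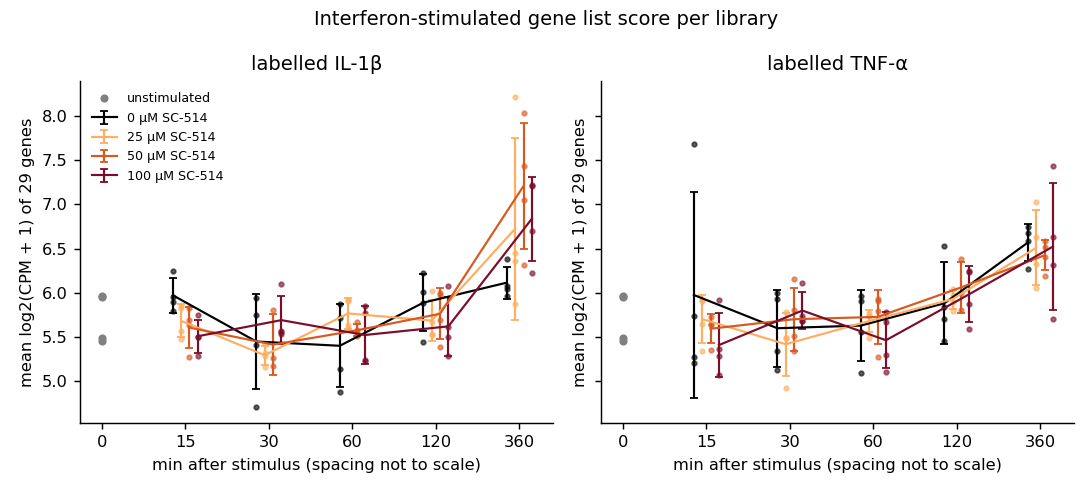
Interferon-stimulated list score, the mean log2(CPM + 1) of 29 genes, by min after stimulus and stimulus label, with points for libraries and lines with SD bars for group means at each SC-514 concentration, without the 2 shallow libraries. At 360 min of IL-1β the means are 6.11 at 0 µM and 6.84 at 100 µM, a difference that did not pass its permutation test.

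In all, 1210, 1078, 1239, 1536 and 1492 genes were higher and 1456, 1346, 1552, 1742 and 1686 lower at 15, 30, 60, 120 and 360 min of IL-1β with the inhibitor. The edgeR quasi-likelihood test gave Il6 at 60 min a Benjamini-Hochberg adjusted p of 1.39e-26 (log2 change -4.47, SE 0.294), lower in 4 of 4 libraries. Without library number 4 the calls at 30 min were 1615, against 2424. With RLE factors 59.4%, 52.7%, 50.4%, 52.8% and 63.6% of the calls were higher, against 45.4%, 44.5%, 44.4%, 46.9% and 46.9% with TMM and 45.8%, 44.8%, 45.1%, 47.1% and 46.6% with RLE without the 2 shallow libraries.

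The same comparison was made in the libraries labelled TNF-α. At 60 min Il6 was at 12.1 ± 5.17 CPM with inhibitor and 301 ± 29.5 CPM without (SD, n = 4), Cxcl5 at 129 ± 16.5 and 985 ± 112 CPM, and Icam1 at 1.41 ± 0.528 and 17.9 ± 9.36 CPM. Nfkbia, at 1816 and 2160 CPM, did not pass the test at 60 min, and at 120 min it was higher with inhibitor, at 780 ± 164 against 364 ± 17.4 CPM. Nfkbiz had log2 changes of -0.75 at 60 min and -1.44 at 30 min.

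Cytokine and chemokine genes had 17 of 22 lower at 60 min of TNF-α with the inhibitor, also 17 adjusted over the list alone (camera adjusted p = 0.000262 with an estimated correlation). Components and feedback genes had 12 of 20 lower and 1 higher, with 14 lower adjusted over the list alone, and Tnfaip3 at -1.51. Adhesion, protease and effector genes had 13 of 21 lower, with 14 adjusted over the list alone, among them Ptges at -2.19, and camera gave adjusted p = 0.0279 with an estimated correlation for either list. Il1a, Acod1 and Nlrp3 were lower by ratios of 63.4 (95% counting interval 17.0 to 531), 34.6 (5.63 to 1420) and 20.9 (5.28 to 181). Serpinb2, Foxa2, Csf3, Il23a and Mmp10 had log2 changes of -4.98, -4.42, -3.93, -3.73 and -3.47. Matrix and contractile genes had 12 of 24 lower and 3 higher, with smooth muscle actin, Acta2, at -0.97 and Ccn1 at 1.18 (camera adjusted p = 0.00146, and adjusted p = 0.564 with an estimated correlation). Among the rising genes were Hist1h1c, at 285 ± 46.0 against 43.4 ± 17.6 CPM, Hist2h3c1 and Hist2h3c2 with 2.72 and 2.36, and Id2 and Smad6, both targets of BMP signalling, with 2.56 and 2.26. The markers Cd14 and Lpl had log2 changes of -1.53 and 0.47.

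At 15 min of TNF-α Egr1 stood at 614 ± 123 CPM with inhibitor and 85.7 ± 19.9 CPM without, 13 of 31 immediate early genes were higher and 3 lower (camera adjusted p = 5.38e-07, and adjusted p = 0.47 with an estimated correlation), 8 of 21 integrated stress response genes were higher and 1 lower (camera adjusted p = 0.000612, and adjusted p = 0.63 with an estimated correlation) and 10 of 14 heat shock genes were lower and 2 higher (camera adjusted p = 4.14e-05, and adjusted p = 0.47 with an estimated correlation). Of 29 interferon-stimulated genes 12 were lower at 15 min, with a list median of -0.77 that was 0.0882 without TNF-α 0 µM 15 min number 4, the library in which Cmpk2 stood at 395 CPM. At 360 min 16 of 22 sterol synthesis genes were lower, with 20 adjusted over the list alone and Cyp51 at -0.85 (camera adjusted p = 3.29e-06, and adjusted p = 0.413 with an estimated correlation). Matrix and contractile genes had 17 of 24 lower at 360 min, with Acta2 at -1.33 and the thrombospondin gene Thbs1 at -1.47 (camera adjusted p = 0.0227 with an estimated correlation), while under IL-1β 9 were lower and 1 higher (camera adjusted p = 0.0126, and adjusted p = 0.627 with an estimated correlation). Hypoxia and glycolysis genes had 15 of 19 lower, with Vegfa at -1.31 (camera adjusted p = 0.0388 with an estimated correlation). Mmp3 fell from 964 ± 80.1 to 121 ± 13.4 CPM at 360 min, Il6 had a log2 change of -4.51, and Il1f6 and Clip4 were lower by ratios of 54.6 (95% counting interval 9.04 to 2230) and 21.3 (6.70 to 108). Cd209c and Megf9 rose by 2.88 and 2.25. At 120 min Egr4 was at least 16.7-fold higher, Kcnk10, which encodes a potassium channel, was lower by a ratio of 85.1 (28.6 to 417), and Plet1 fell by 4.47, while at 30 min Il6 fell by 3.99.

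The counts with TNF-α were 968, 767, 896, 1236 and 1222 higher and 1425, 1158, 1468, 1620 and 1661 lower genes at the 5 times. For Il6 at 60 min the edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 1.56e-30 (log2 change -4.55, SE 0.270), lower in 4 of 4 libraries. With RLE factors 60.9%, 50.2%, 56.4%, 59.1% and 68.7% of the calls were higher, against 40.5%, 39.8%, 37.9%, 43.3% and 42.4% with TMM and 41.6%, 39.5%, 40.5%, 40.4% and 40.7% with RLE without the 2 shallow libraries.

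**Figure D4:**
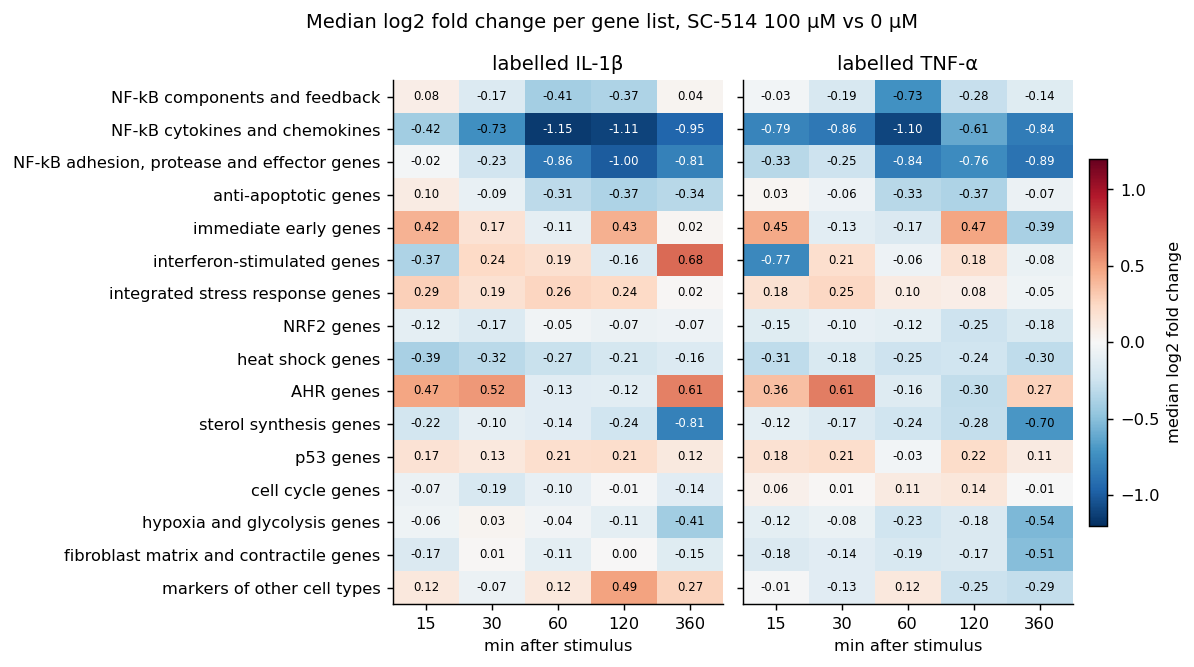
Heat map of the median log2 fold change of each gene list at 100 µM against 0 µM SC-514, by min after stimulus and stimulus label, with red for higher and blue for lower. The cytokine and chemokine list is at -1.15 at 60 min of IL-1β and -1.10 at 60 min of TNF-α, and the sterol synthesis list at -0.81 and -0.70 at 360 min.

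The genes that changed with SC-514 at 100 µM overlapped between the stimuli, whose comparisons shared no libraries. At 15 min 567 genes were higher under both labels, where independent lists would share 109, and 926 were lower under both, against 193, while 7 went opposite ways. At 60 min 492 were higher and 975 lower under both, and 20 went opposite ways. Log2 changes correlated across genes with r = 0.731 at 15 min and 0.641 at 360 min, where genes are not independent replicates.

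Lower concentrations of SC-514 were tested over the 5 times together, to see whether the changes scaled with dose. The mean change of Il6 was -1.49 at 25 µM and -2.41 at 50 µM on the log2 scale in the libraries labelled IL-1β, and -1.14 and -2.21 in those labelled TNF-α. Cxcl1 changed by -0.97 and -1.23, and by -0.59 and -1.04. Egr1 went the other way, with 1.02 and 1.45, and with 0.74 and 1.06. Single times could differ from these means. At 120 min of TNF-α Cxcl1 changed by 0.16 and 0.08 at 25 and 50 µM, and Il6 by 0.05 and -0.62. Egr1 changed by -0.04 and 0.03 at 60 min of TNF-α. The F test asks for a change at any time, so the sign of a mean is not itself tested. Of the 22 cytokine and chemokine genes, 9 passed with a lower mean at 25 µM and 16 at 50 µM under IL-1β, and 9 and 18 under TNF-α, while 5 and 3 passed with a higher mean under IL-1β and 5 and 1 under TNF-α. Immediate early genes had 25 and 23 of 31 with a higher mean and 3 and 6 with a lower one under IL-1β, and 22 and 18 higher and 4 and 10 lower under TNF-α. Sterol synthesis genes had 11 and 16 of 22 with a lower mean, and 10 and 15. Interferon-stimulated genes had 10 and 11 of 29 with a higher mean and 5 and 6 with a lower one under IL-1β. They had 0 and 2 higher and 4 and 8 lower under TNF-α, and whether this differed between the stimuli was not tested at these concentrations. Of all tested genes, 28.7% and 40% passed at 25 and 50 µM under IL-1β, and 23.8% and 35.9% under TNF-α. Lists were not compared with all other genes in these F tests, so their counts alone do not show a response particular to a list.

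The F tests called 3086 genes at 25 µM and 4304 at 50 µM under IL-1β, and 2564 and 3862 under TNF-α. The edgeR quasi-likelihood F test gave Il6 Benjamini-Hochberg adjusted p-values of 1.29e-20, 2.14e-32, 2.66e-15 and 2.56e-30 in the same order. With RLE factors 51.7% of the calls at 50 µM under IL-1β and 50.9% and 57.3% at 25 and 50 µM under TNF-α were higher, against 48%, 46.6% and 45.4% with TMM and 47%, 44.9% and 45.8% with RLE without the 2 shallow libraries. The kinase gene Ikbkb itself, at 54.7 ± 11.7 CPM in the unstimulated libraries, passed the test in none of the 20 single-time comparisons, and among these F tests passed with -0.23 at 50 µM under IL-1β.

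The NF-κB target score summarised the 63 genes of the 3 NF-κB lists. Without inhibitor it went from 5.12 ± 0.0462 in the unstimulated group to 6.52 ± 0.114 at 60 min of IL-1β and 6.90 ± 0.0604 at 60 min of TNF-α (SD, n = 4). At 60 min of IL-1β it differed from 0 µM by -0.341, -0.643 and -0.989 at 25, 50 and 100 µM, and at 60 min of TNF-α by -0.246, -0.577 and -1.05. In two-sided exact permutation tests of 4 against 4 libraries, 22 of 30 differences passed after Benjamini-Hochberg adjustment, 5, 7 and 10 of 10 at 25, 50 and 100 µM, each with p = 0.0286, the smallest such a test can give, and an adjusted p of 0.039. The difference at 25 µM and 60 min of TNF-α did not pass (exact p = 0.0571, adjusted p = 0.0686). At 25 µM and 15 min the score was higher by 0.169 under IL-1β (exact p = 0.0571, adjusted p = 0.0686) and by 0.0991 under TNF-α (exact p = 0.286, adjusted p = 0.296), and neither passed. The 50 µM groups at 30 min of IL-1β and 120 min of TNF-α each held a shallow library. Their differences were -0.824 and -1.27, and -0.22 and -0.356 without the shallow library. Genes picked as induced at 60 min in libraries numbered 1 and 2, and measured in numbers 3 and 4, had median changes of -0.161, -0.389 and -0.832 for 107 genes under IL-1β and -0.167, -0.439 and -0.742 for 167 genes under TNF-α at the 3 concentrations.

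**Figure D5:**
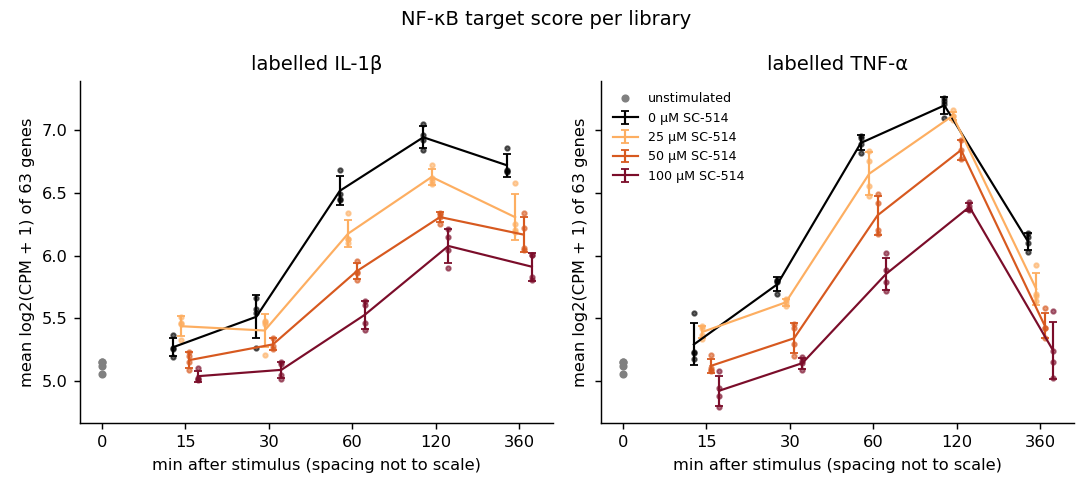
NF-κB target score, the mean log2(CPM + 1) of 63 genes, by min after stimulus and stimulus label, with points for libraries and lines with SD bars for group means at each SC-514 concentration, without the 2 shallow libraries. At 60 min of TNF-α the means run from 6.90 at 0 µM to 5.85 at 100 µM.

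Whether the change with SC-514 at 100 µM differed between the 2 stimuli was tested over the 5 times. The F test called 504 genes, 315 with a more positive effect under IL-1β and 189 with a more negative one. Of the NF-κB targets, 2 of 22 cytokine and chemokine genes were higher and 1 lower, 3 of 21 effector genes higher and 1 lower, and 1 of 20 component genes each way, and 10, 11 and 5 passed adjusted over the list alone. Cxcl2 had a mean difference of -1.46, with 2.58 and 0.88 at 15 and 30 min, -1.33 and -2.29 at 60 and 120 min and -7.11 at 360 min. Its values at 15, 30 and 360 min involve groups with at most 3 counts and depend on how the model treats these, so that the mean, which rests mostly on 360 min, is no measure of size. The genes with the smallest p in the positive direction included Rplp1, a ribosomal protein gene, Vim, the gene of the fibroblast filament protein vimentin, H3f3a and Fth1, with mean differences of 0.45, 0.37, 0.38 and 0.36. Cd63, Eef1g, Cox7c and Lgals1 had 0.32, 0.38, 0.58 and 0.26. In the negative direction stood Ctnnb1, which encodes β-catenin, with -0.48, and the syndecan gene Sdc1 with -0.45. Alyref had -0.38, Atp5k -0.33, Ap2a1 -0.76 and Cacnb3 -0.46. Enoph1 had a mean of -0.43 but changed sign, with 1.44 and 0.20 at 15 and 30 min. At 60, 120 and 360 min it had -1.41, -1.27 and -1.13.

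The edgeR quasi-likelihood F test gave Rplp1 a Benjamini-Hochberg adjusted p of 1.09e-17 and Cxcl2 1.51e-07. With the log2 library total as a covariate 258 genes were called, 225 of them among the 504, and without library number 3 or 4 there were 231 and 261. With RLE factors 46% of the calls were more positive under IL-1β, against 62.5% with TMM and 63.9% with RLE without the 2 shallow libraries. Of the matrix and contractile genes 8 of 24 passed with a more positive value and 0 with a more negative one.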

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

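The weighing tests on Nfkbiz and Zc3h12a, on a blocked stimulus response, on depth and on abundant transcripts were chosen after the results were seen, while the test of a constant vehicle amount and the other splits of the libraries were chosen before.

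Libraries far from the other 3 of their group were looked for with Dixon's test, which chance passes in about 1 of 20 groups. Of 41 groups tested for total counts, 2 had such a library, IL-1β 50 µM 30 min number 1 with 12191 counts and TNF-α 50 µM 120 min number 1 with 3839. Of 41 groups tested for the NF-κB target score, 8 had one. Both shallow libraries were among them, with scores of 2.88 and 3.2. The others were IL-1β 0 µM 360 min number 1 at 6.86, IL-1β 25 µM 30 min number 4 at 5.21, IL-1β 25 µM 60 min number 1 at 6.34, IL-1β 25 µM 360 min number 1 at 6.58, TNF-α 0 µM 15 min number 4 at 5.54 and TNF-α 0 µM 30 min number 2 at 5.69. Of 41 groups tested for the interferon-stimulated list score, 4 had one, IL-1β 100 µM 30 min number 4 at 6.1, TNF-α 25 µM 60 min number 3 at 5.49, TNF-α 100 µM 30 min number 1 at 6.11 and the shallow TNF-α library at 0.966.

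Among 227 groups tested for single genes, 13 had a library far from the others, close to the share chance gives. In TNF-α 0 µM 15 min number 4, Cmpk2, an interferon-stimulated gene, stood at 395 CPM against 18.5 to 27.9 in the others. Number 2 was apart for Romo1 at 39.6 CPM in IL-1β 0 µM 15 min, Nfia at 188 and Pou2f2 at 31.1 CPM in the unstimulated group, Il1a at 11.6 CPM in IL-1β 0 µM 120 min, Egr2 at 111 and 222 CPM in IL-1β and TNF-α 0 µM 60 min, Grhl1 at 4.58 CPM in TNF-α 100 µM 30 min and Hist2h3c1 at 22.3 CPM in TNF-α 100 µM 60 min. The remaining ones were Il1a at 28.5 CPM in TNF-α 0 µM 60 min number 1, Nlrp3 at 2.27 CPM in number 3 of the same group, Cxcl9 at 26 CPM in IL-1β 0 µM 60 min number 1 and Fosb at 42.6 CPM in TNF-α 100 µM 30 min number 4.

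The effect of SC-514 at 100 µM differed between the stimulus labels for 504 genes by the F test of the difference itself. Mean log2 differences were 0.454 for Rplp1, 0.368 for Vim, 0.378 for H3f3a, 0.356 for Fth1, 0.316 for Cd63, 0.375 for Eef1g, 0.58 for Cox7c and 0.263 for Lgals1. They were -0.434 for Enoph1, -0.454 for Sdc1, -0.481 for Ctnnb1, -0.385 for Alyref, -1.46 for Cxcl2, -0.33 for Atp5k, -0.759 for Ap2a1 and -0.458 for Cacnb3. The mean of Cxcl2 rests mostly on -7.11 at 360 min, which involves groups with at most 3 counts. That of Enoph1 joins 1.44 at 15 min with -1.41 at 60 min and describes neither.

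Nfkbiz and Zc3h12a were higher in the libraries labelled TNF-α. A difference between the library sets of both labels that was alike at all times would be as wide at 15 min. The log2 difference of Nfkbiz widened from 15 to 60 min by 2.38 (SE 0.263), which argues against it for this gene. That of Zc3h12a widened by 0.976 (SE 0.302), with an adjusted p of 0.534 in edgeR, which does not decide. Both genes were picked by their difference in these same libraries, and a set difference that varies with time stays open. A misplaced library is argued against by the lowest TNF-α library at 60 min, which was above the highest IL-1β library by ratios of 7.92 and 1.79. Of 6 listed transcripts known to be stabilised by IL-1, 4 were higher in the libraries labelled TNF-α, but 2 of these are Nfkbiz and Zc3h12a themselves, and of the others Csf3 and Cxcl1 were higher while Lcn2 and Il6 did not pass. An exchange of the stimulus labels or a stronger stimulus would go this way. These values cannot tell such explanations apart, so exchanged labels stay open.

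With SC-514 at 100 µM 2666 and 2393 genes were called at 15 min under IL-1β and TNF-α, after a further 1 hour with the inhibitor before the stimulus. Loss of the stimulus response would bring the libraries back to the unstimulated level and is argued against as the main source, because the genes picked under IL-1β and measured under TNF-α had a median change against the unstimulated libraries of 0.92 of that against 0 µM (0.324 to 0.363 in single libraries on the log2 scale), and those picked under TNF-α and measured under IL-1β 0.845 (0.355 to 0.361), while the 0.338% and 0.46% of them called for the stimulus do not decide, since 18 and 20 genes were called for it. Depth is argued against as the whole cause by 99% and 90.3% of the calls left with log2 library total in the fit, while the correlation across genes of 0.731 between the labels does not decide, since depth differed in the same direction under both, by 0.0558 and 0.321 on the log2 scale between 100 and 0 µM. A vehicle at a constant amount would give equal changes at each concentration, and the median change at 25 µM was 0.588 of that at 100 µM. A vehicle that scaled with the dose stays open, so the inhibitor itself may or may not be the cause, without a group given the inhibitor alone.

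In the inhibitor difference between labels 72 of the 200 most abundant genes were called (36%, 69 of them positive) against 4.09% of other genes, which held 432 of the 504 calls, and that abundant genes are more easily called was not allowed for. The share of counts in these genes fell with library total over 162 libraries (r = -0.699, rho = -0.634, permutation p = 1e-05 for each, the smallest such a test can give here, r = -0.705 without the 2 farthest), and did so within groups (r = -0.477, rho = -0.485, permutation p = 1e-05 for each, r = -0.489 without the 2 farthest). Median library totals went from 1406626 at 0 µM to 1130539.5 at 100 µM under IL-1β, and from 1211517.5 to 1564485 under TNF-α. The mean share of counts in the 200 genes went from 22.2% to 22% and from 22.5% to 21.1%. With all times pooled, depth thus changed in opposite directions under the labels, along with the difference tested. With log2 library total in the fit 79.2% of the 72 calls were left, and their median difference went from 0.247 to 0.251. That fit held the 2 shallow libraries, whose totals lie far below all others, while share and depth were related over the 162 others. It was not run without the shallow ones, so it cannot decide whether depth is the whole cause in these genes. Of the 432 calls in other genes 168 were left. The 15 calls that ended had a median of 0.169 (SD 0.175) before and 0.147 (SD 0.143) after. Their median adjusted p in edgeR went from 0.00498 to 0.0987. The 264 that ended in other genes had a median absolute difference of 0.321 (SD 0.254) before and 0.274 (SD 0.251) after. Their median adjusted p in edgeR went from 0.0202 to 0.15. Depth stays open for the calls that were left as well as for those that ended. An inhibitor acting on the stimulus response may widen the difference with time, but the ratio of 15 to 360 min, 0.439, cannot tell this from a library effect that also varies with time.

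Other splits of the same libraries were counted in limma-trend fits. In each of the 20 single-time comparisons 1 of 35 splits, the real one, gave as many genes, the fewest such a test can give. This argues against chance as the source of the limma-trend counts as a whole, and says nothing of single genes. These counts are not those of edgeR, which called 18 genes at 15 min of IL-1β. For IL-1β alone the real counts were 103, 138, 428, 1516 and 2410 at the 5 times and the highest others 22, 24, 33, 0 and 0, and for TNF-α alone 12, 100, 619, 1255 and 735 against 1, 29, 8, 8 and 0. With SC-514 at 100 µM they were 2877, 2262, 2681, 2904 and 2418 against 0, 4, 5, 0 and 0 under IL-1β, and 2037, 1695, 1894, 2285 and 2859 against 8, 9, 9, 7 and 3 under TNF-α. In the F tests 1 of 100 splits drawn gave as many genes for 25 and 50 µM under IL-1β (2945 against 57, 1607 against 67), for the same under TNF-α (2204 against 90, 425 against 5) and for IL-1β against TNF-α (885, where the highest other split drawn gave 58.1% as many). Unlike in edgeR, fewer genes were called here at 50 than at 25 µM. The 50 µM groups held the 2 shallow libraries, and whether these caused it was not tested. For the difference of the 100 µM effect 2 of 100 splits drawn gave as many genes, and the other one gave 937 against the real 418. These splits exchanged 0 and 100 µM libraries within each stimulus and time, so they also broke up the inhibitor effect that both stimuli share. They cannot decide whether chance gave the calls for the difference.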

How the results depend on the processing

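The fits without the 2 shallow libraries, with log2 library total as a covariate and without single libraries of a group were chosen after the data were seen, and the other alternatives before. The library number as a block left all 28 counts within 1.5 times of those reported, with 180 of 180 named genes and 432 of 438 named gene results on the same side of the threshold. It gave 145 calls of gene lists, since 2 of the 146 were lost and 1 was new. RLE size factors left 28 counts and 432 of 438 named gene results the same, and turned no list or named gene around.

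Without a filter on low counts the calls at 15 and 30 min were 141 and 272 for IL-1β and 270 and 187 for TNF-α. DESeq2 called 11, 57 and 230 genes at 15, 30 and 60 min of IL-1β, and limma-voom 13 at 15 min of TNF-α. A fit of only the groups compared called 117 genes at 15 min of IL-1β and 115 of 180 named genes. There 323 of the 438 named gene results stayed on the same side of the threshold, 12 gained a call, 16 lost it and 1 turned around, and the others had no value, since the filter on low counts within those groups left the gene out. With the 15 min libraries as baseline 25 and 206 genes were called at 30 and 60 min of IL-1β, and 35, 328 and 273 at 30, 60 and 360 min of TNF-α. With log2 library total as a covariate the difference between stimuli had 258 genes. With an estimated correlation 48 of the 146 calls of gene lists were left. In each case the cause was not tested.

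Leaving out 1 library number gave 1 to 10, 44 to 82, 228 to 278 and 854 to 1054 genes at 15, 30, 60 and 120 min of IL-1β, 3 to 32, 46 to 95, 380 to 464 and 292 to 457 at 15, 30, 60 and 360 min of TNF-α, 1615 to 2025 for 100 µM at 30 min of IL-1β, and 231 to 497 for the difference between stimuli, where fits without 1 library of a group are included. Without TNF-α 0 µM 15 min number 4 alone there were 6 at 15 min of TNF-α. Fewer libraries lower the power of these fits.

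Some values turned around, and the cause was not tested except where a library is named. Ccdc22 at 60 min of IL-1β was 0.104 with the 15 min baseline. The mean difference of Tnfaip2 between stimuli, near 0 as reported, was -0.000837 in the fit of only the groups compared, -0.00169 without the 2 shallow libraries, -0.00617 with log2 library total, -0.0106 without TNF-α 0 µM 15 min number 4 and -0.0329 to 0.0306 without 1 library number. That of Ndrg1 ran from -0.137 to 0.0453. The interferon-stimulated list at 15 min rested on TNF-α 0 µM 15 min number 4: its median was -0.284 for TNF-α and 0.0882 for 100 µM without that library, and -0.376 to 0.951 and -1.2 to 0.148 without 1 library number. The matrix list at 30 min of IL-1β, whose test changed direction without number 1, had medians of 0.0205 to 0.219. The median SC-514 change at 25 µM and 30 min of IL-1β was 0 for the NF-κB lists and -0.221 for induced genes picked in numbers 1 and 2 and measured in 3 and 4, which are different genes.

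Of 30 NF-κB target score differences, 22 passed as reported. The differences at 50 µM were -0.824 at 30 min of IL-1β and -1.27 at 120 min of TNF-α, and -0.22 and -0.356 without the shallow libraries. At 100 µM leaving out 1 library number gave -1.05 to -0.957 at 60 min of IL-1β and -1.08 to -1.01 at 60 min of TNF-α. Depth limits genes near the floor, where 3 counts equalled 1.22 to 3.23 CPM outside the shallow libraries.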
